A study of Mus musculus with 6 samples.

How the data were processed

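RNA was measured by sequencing in 6 libraries from adult C57/BL6 mice, 3 from the carotid body and 3 from the adrenal medulla. The carotid body is a small chemosensory organ at the carotid bifurcation, and the adrenal medulla is the catecholamine-secreting core of the adrenal gland. Per the labels' design note, a pool comes from 10 mice, with 18 carotid bodies or 10 adrenal medullas, so each library is 1 pool and n counts pools. Per the labels' protocols, dissected tissue was kept in RNAlater, RNA was purified on RNeasy Micro columns, and total RNA was amplified with the Amino Allyl MessageAmp II aRNA kit, fragmented and made into Illumina libraries. That amplification starts from the poly(A) tail, and the protocols do not say whether strand was kept. Reads were aligned with Bowtie 0.9.8 to the mouse build mm9, per the submitters' processing notes.

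The deposited table holds RPKM values made by the authors, reads per kilobase of mRNA scaled to the mapped reads of the library, for 23511 of its 26728 entries. RPKM multiplied by the listed mRNA length and divided by the smallest such product above 0 of the library, taken as 1 read, gave a whole number, within 0.01, for 106276 of 106276 values above 0. The size of that product gave the denominator of the RPKM values, in reads. The remaining 3217 entries have no mRNA length, 3164 of them predicted transcripts and 53 curated ones, and their values are raw read counts. With those counts included, the reads of all entries summed exactly to the denominator of the authors' RPKM in 6 of 6 libraries. The recovered depth was 13266225 to 16445925 reads per library. At 2 kb, 1 read corresponds to 0.0304 to 0.0377 RPKM, and an mRNA of that length at 3.77 RPKM is read about 100 times, which gives a counting precision of 10%. Amplified reads carry no molecular identifiers, so such a precision covers counting error only. The entries without a length were kept out of the main comparison and are described separately. Gene symbols were taken from the deposited table. The RefSeq gene table of GRCm38.p6 was used for names and neighbouring genes only, since it is a later build, and it listed the accessions of 23347 entries, 21642 of them under the same symbol.

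The main comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with the empirical Bayes variance trend and no block, over the 13357 genes that reached 1 RPKM in at least 3 libraries. A log2 difference is carotid body minus adrenal medulla throughout, on the log2(RPKM + 1) scale, which understates the difference of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and the moderated test had 8.47 degrees of freedom. Genes over 2-fold apart were called with limma's treat against a log2 difference of 1. Gene lists were tested with limma's camera, a test of a list against all other genes, at its preset correlation of 0.01 and adjusted over the 36 of 38 lists with at least 5 tested members. All adjusted p-values below come from limma. They measure only the spread between these pools. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

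The test, the filter, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 10 genes with the largest log2 difference in each direction among called genes of at least 10 RPKM in the higher tissue whose 3 libraries all lay above those of the other tissue. It also named 19 genes whatever their values, from Th to Olfr78, and up to 4 called members per list with the largest absolute log2 difference. Not every gene the rule allows is printed. Where a list had more examples than space, those that stayed called in every alternative that tested them were preferred, a preference set after the values were seen. Members outside the rule are named, also after their values were seen, only to spell out a small count or where the text says so. Of the marker lists, the smooth muscle list shares Rgs5 with the RGS list, the cortex list shares Mc2r with the receptor list, and Adm is in both the neuropeptide and the HIF target list. Lists of mast cell, lymphatic, adrenal X-zone and further brown fat genes were added after the data were examined.

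The comparison was tested on simulated data drawn for the same 13357 genes, with 200 genes changed between 3 libraries and 3. It recovered 34 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, and 12 of its 145 calls, 8.28%, were unchanged genes. Of 30 random lists, camera called 0. The simulated genes were drawn independently of each other, without shared pool effects. That 0 therefore says nothing about lists whose genes vary together. In the data 21.9% of genes were called, a far larger share than was changed in the simulation. The Benjamini-Hochberg cutoff depends on that share, so the recoveries above are not those of the main comparison. Simulated genes of similar level were also given the same spread, unlike real genes.

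Both tissues carry pool numbers 1 to 3, and a possible pairing was examined on the deviations of each library from its tissue's mean, across genes. Same-numbered libraries correlated at 0.259, 0.128 and 0.473, all above 0.1. A fit with the pool number as a replicate block was therefore set beside the main one. Carotid body pool 2 also correlated with adrenal medulla pool 1, at 0.291, and with the length trend removed the same-number values were 0.276, 0.0936 and 0.425. Genes are not independent replicates in such correlations, so the values cannot settle whether equal numbers mean the same mice. For the libraries numbered 3, Y-linked reads given below argue against it. Deviations followed mRNA length in opposite ways, from a Spearman correlation of 0.334 in adrenal medulla pool 1 to -0.351 in adrenal medulla pool 3, while the difference between tissues followed length at 0.0934. Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 RPKM, median-ratio and quantile scaling, other variance settings, the replicate block, testing every entry of the table, and leaving out each library in turn. For lists, camera with a correlation estimated per list and fry, which asks whether a list's own genes move one way on balance, were run too. After the data were examined, 3 more were added: limma's voom on the recovered reads, the replicate block with the length trend removed, and a fit without carotid body pool 2 and adrenal medulla pool 3 together.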

Results

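Transcripts of the carotid body and the adrenal medulla were compared in 3 pools of each tissue. Both organs hold catecholamine-secreting cells of neural crest origin, and the comparison asks which genes mark the carotid body, the sensor of arterial oxygen, against a related tissue that is less sensitive to acute hypoxia in adults. Carotid body pools 1, 2 and 3 held 14508925, 13266225 and 15570292 reads, and adrenal medulla pools 1, 2 and 3 held 13435782, 14275163 and 16445925. The 10 most abundant entries took 4.54% to 9.16% of the reads of a library. Pools of the same tissue correlated at 0.930 to 0.979 across genes on the log2 scale, and pools of different tissues at 0.826 to 0.859. Replicate pools differed by more than sampling noise, with a chi-square per gene of 42.0 to 159.

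Of 13357 genes tested, 1896 were higher in the carotid body and 1033 were higher in the adrenal medulla, and 485 and 237 of them differed by more than 2-fold. All 3 libraries of one tissue lay above all 3 of the other for 37.0% of genes, where chance gives 10%. This held for every called gene of the naming rule below except the haemoglobin genes Hba-a1 and Hba-a2. The rule required it of the 10 top genes in each direction and took the largest called differences of each list. The separation of the named genes therefore adds no support. Calls leaned to the carotid body at 64.7%, against 60.1% under median-ratio scaling, 55.0% under quantile scaling and 57.7% to 68.45% without 1 library. Adrenal medulla pool 3 lacked Y-linked reads and carotid body pool 2 was rich in fat transcripts. Without both of them, limma called 1928 genes higher in the carotid body and 2067 higher in the adrenal medulla, or 48.3% to the carotid body; the cause was not tested. The libraries are of whole tissue, and cell type markers differed between them, as given below for each list. Of 36 gene lists, camera called 15 at its preset correlation and 2 with an estimated correlation, and 1 other division of the same 6 libraries called 16 at the preset one. That division mixes the tissues unequally and keeps part of their difference, so its 16 calls are no measure of chance.

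Higd1c, a member of the hypoxia-inducible HIG1 family of mitochondrial proteins, led the carotid body at 498 ± 58.5 RPKM against 1.79 ± 0.614 in the adrenal medulla (SD, n = 3 pools each), a log2 difference of 7.50 ± 0.24 (SE). Rgs5, a brake on G protein signalling that is abundant in pericytes, reached 1669 ± 177 RPKM against 29.5 ± 7.12 (log2 5.80, limma adjusted p = 9.89e-06). The olfactory receptor gene Olfr78 stood at 101 ± 29.2 against 1.08 ± 0.591 RPKM (log2 5.61, adjusted p = 1.44e-05). Gap43, a protein of growing axons, was higher by 5.79 on the log2 scale, at 382 ± 49.4 against 5.93 ± 0.817 RPKM. The matrix genes Pcolce2, a procollagen processing enhancer, and Mfap5, a microfibril component, were higher by 6.19 and 5.63. Ly6h, which encodes a membrane-anchored Ly6 protein, the methyltransferase gene Inmt and the secreted factor Cytl1 were higher by 5.99, 5.87 and 5.80. The value of Inmt became 6.61 without adrenal medulla pool 1, and that of Ly6h 6.79 without carotid body pool 2 and adrenal medulla pool 3. AB099516, at 753 ± 172 against 3.63 ± 1.45 RPKM (log2 7.38), is named Methig1 in the GRCm38.p6 RefSeq table and spans both Higd1c and Mettl7a2. Reads of AB099516 and Higd1c cannot be separated in the deposited values.

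**Figure D1:**
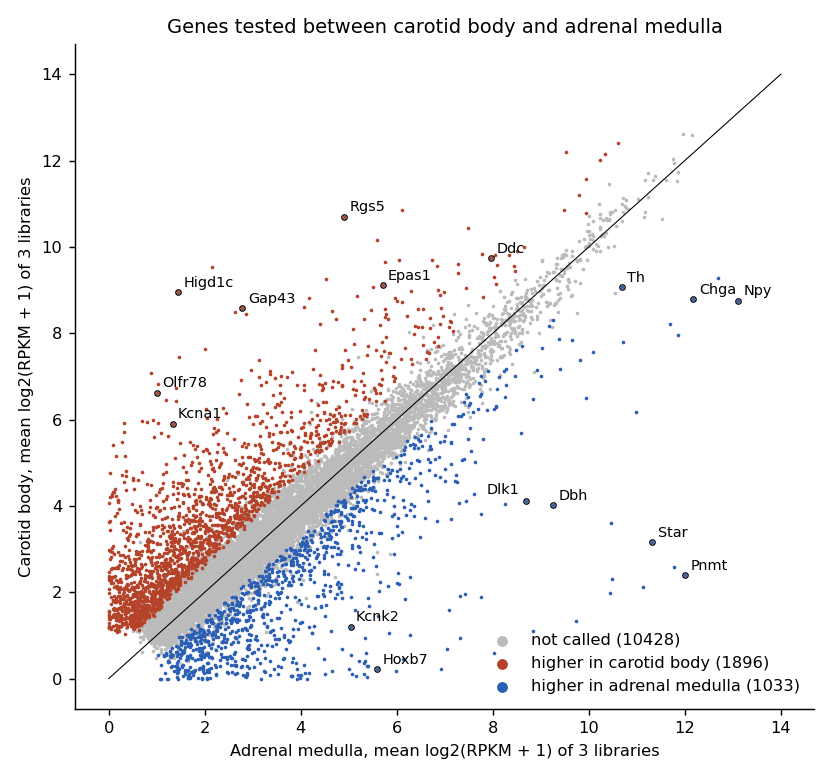
Mean log2(RPKM + 1) of the 3 adrenal medulla libraries (horizontal axis) against that of the 3 carotid body libraries (vertical axis) for each of the 13357 genes tested, with the line of equal level. Red points are the 1896 genes called higher in the carotid body and blue points the 1033 called higher in the adrenal medulla; Higd1c and Rgs5 lie far above the line, Pnmt and Star far below it.

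The adrenal medulla was led by Pnmt, the enzyme that turns noradrenaline into adrenaline, and by genes of steroid synthesis. Pnmt stood at 4325 ± 1669 RPKM against 6.84 ± 8.59 in the carotid body (SD, n = 3), a log2 difference of -9.60 ± 0.67 (SE). Star, which moves cholesterol into mitochondria, was at 2582 ± 402 against 11.8 ± 13.3 RPKM (log2 -8.16). Cyp11a1, which makes the first steroid from cholesterol, was at 1440 ± 88.6 against 5.14 ± 5.15 RPKM (log2 -8.19), and Cyp11b1, which completes corticosterone, differed by -8.41. Hsd3b1 (-9.19), Akr1cl (-8.45), Mgarp (-7.74), Srd5a2 (-7.43) and Cyp21a1 (-6.86) followed, with Akr1b7 at 2439 ± 1187 against 7.11 ± 10.5 RPKM. Hsd3b1 and Akr1cl belong to families of similar genes that can share reads, so their values are uncertain. All 16 tested adrenal cortex markers were higher in the adrenal medulla libraries, 16 also when adjusted over the list alone, with a median log2 difference of -5.25. The list passed limma's camera at an adjusted p of 2.70e-18, and at adjusted p = 0.0480 with an estimated correlation.

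The size of these differences depended on single pools. Adrenal transcript levels were compared over 10 genes of at least 300 RPKM in the adrenal medulla and under 2% of that in each carotid body library. Akr1c18, high in adrenal medulla pool 3 only, was left out by name. Over these 10 genes, carotid body pool 1 had a median of 0.763% of the adrenal level, against 0.0701% in pool 2 and 0.0596% in pool 3. Without carotid body pool 1, the log2 differences became -10.48 for Pnmt, -10.39 for Hsd3b1, -10.11 for Akr1b7, -9.29 for Akr1cl, -9.21 for Cyp11b1, -8.99 for Star, -8.83 for Cyp11a1, -8.02 for Srd5a2 and -7.49 for Cyp21a1. Hsd3b1 became -8.44 without carotid body pool 3. Srd5a2 became -6.68 without adrenal medulla pool 2 and -8.71 without adrenal medulla pool 3. Without carotid body pool 2 and adrenal medulla pool 3, where pool 1 is 1 of 2 carotid body libraries, Pnmt was at -8.90, Akr1cl at -7.61, Cyp21a1 at -5.94 and Srd5a2 at -8.41.

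Genes of catecholamine synthesis split the tissues. Ddc, which makes dopamine from L-DOPA, was higher in the carotid body, at 855 ± 71.5 against 250 ± 36.3 RPKM (log2 1.78 ± 0.24, limma adjusted p = 9.15e-04). Dbh, which makes noradrenaline from dopamine, was lower there, at 15.9 ± 5.69 against 656 ± 264 RPKM (log2 -5.24, adjusted p = 4.76e-05), as was the vesicular monoamine transporter gene Slc18a1 (-2.87). Th, the rate-limiting enzyme of the pathway, was at 543 ± 106 against 1793 ± 821 RPKM (log2 -1.61, adjusted p = 0.0218). The call of Th was lost without carotid body pool 1 (adjusted p = 0.0693), without carotid body pool 2 (0.0611), without adrenal medulla pool 2 (0.0869) and without both carotid body pool 2 and adrenal medulla pool 3 (0.0878). Slc18a2, the second vesicular transporter, was not called (-0.33, adjusted p = 0.631), though without adrenal medulla pool 3 it differed by -0.79 (adjusted p = 0.0470), and by -0.94 (0.0264) without carotid body pool 2 as well. Of 14 tested members of the list, 1 was higher in the carotid body, 6 were higher in the adrenal medulla and 7 were not called; adjusted over the list alone the counts were again 1 and 6. The adrenal medulla libraries behind these values also held transcripts of cortex markers, with Star at 2582 ± 402 RPKM. The camera adjusted p of the list was 0.00241 at the preset correlation, and the call ended at adjusted p = 0.228 with an estimated correlation.

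Chga, the granule matrix protein chromogranin A, was at 450 ± 107 RPKM in the carotid body and 4743 ± 1160 in the adrenal medulla (log2 -3.39 ± 0.33, adjusted p = 1.53e-04). The granule proteins Chgb and Scg2 (-3.42 and -3.48) and the prohormone convertase Pcsk1 (-4.15) differed in the same direction. Among 25 tested genes of secretory granules and exocytosis, 0 were higher in the carotid body, 8 were higher in the adrenal medulla and 17 were not called, with 9 in the adrenal medulla adjusted over the list alone. The libraries also differed in other cell types, with 16 of 16 cortex markers higher in the adrenal medulla, and 15 of 15 glia and 16 of 18 fibroblast markers higher in the carotid body. The granule list had a camera adjusted p of 1.41e-04 and lost its call at adjusted p = 0.302 with an estimated correlation. Neuropeptide genes went both ways. Npy (-4.35, at 457 ± 182 against 9578 ± 4198 RPKM), Gal (-3.45), Cartpt (-3.59) and Edn3 (-4.79) were higher in the adrenal medulla, and Edn1, Nmu, Penk, Adm and Nmb were higher in the carotid body. That left 5 of 14 not called, with the same 5 and 4 adjusted over the list alone, and camera gave an adjusted p of 0.970. The list's median was 0.48 and its mean -0.32, with camera's direction following the median. The transcription factor genes Gata3 (-4.32), Tfap2b (-2.91), Hand1 (-2.85) and Gata2 (-2.11), which act in sympathoadrenal development, were higher in the adrenal medulla. The other 9 of 13 in their list were not called, and 4 were called adjusted over the list alone. Camera gave 0.00372 for this list, and adjusted p = 0.493 with an estimated correlation.

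**Figure D2:**
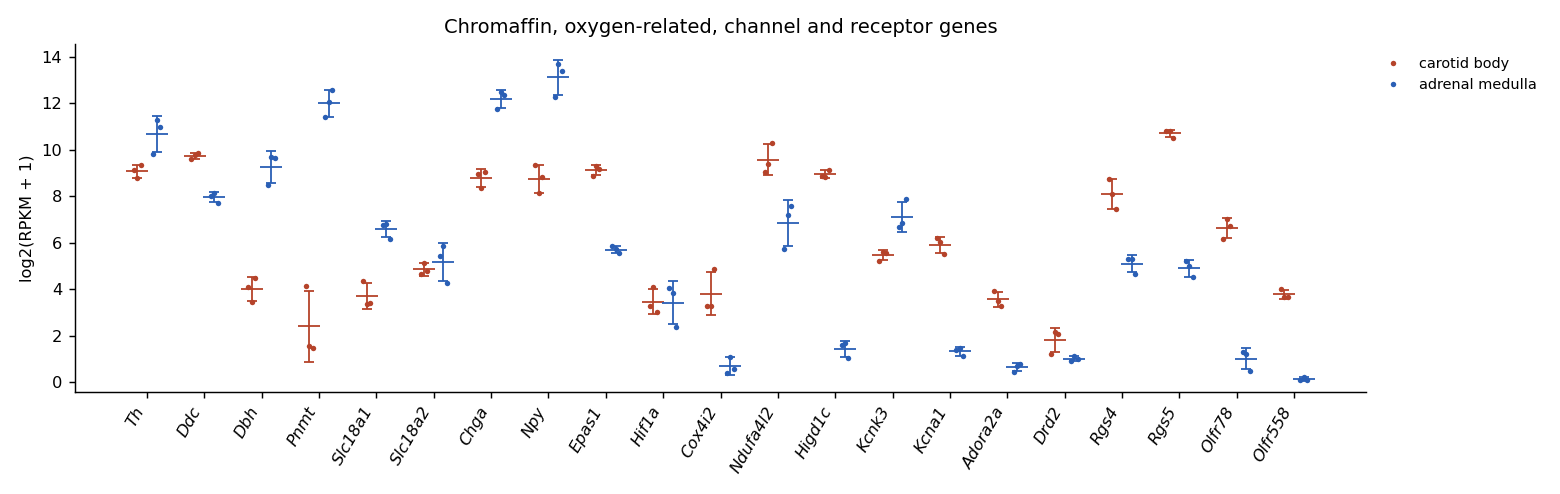
Log2(RPKM + 1) of chromaffin, oxygen-related, channel and receptor genes in each of the 3 carotid body (red) and 3 adrenal medulla (blue) libraries, with bars at the mean ± SD. Ddc, Epas1, Higd1c and Olfr78 lie higher in the carotid body, Dbh, Pnmt and Chga lie higher in the adrenal medulla, and Hif1a and Slc18a2 overlap.

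Epas1, which encodes the hypoxia-inducible factor subunit HIF-2alpha, was at 556 ± 82.0 RPKM in the carotid body and 51.3 ± 5.32 in the adrenal medulla (SD, n = 3; log2 3.41 ± 0.23, limma adjusted p = 2.71e-05). Hif1a, its HIF-1alpha counterpart, did not differ by the test, at 10.6 ± 4.65 against 11.1 ± 6.08 RPKM (log2 0.05, adjusted p = 0.966). Its direction depended on single libraries, with -0.26 without carotid body pool 2 and -0.48 without adrenal medulla pool 3. Without both it was called lower in the carotid body (-0.79, adjusted p = 0.0383). Epas1 was the 1 gene called of 8 tested in the HIF pathway, and also the 1 adjusted over the list alone; Hif1a, Arnt, Vhl, Egln1 and others made up the 7 not called (camera adjusted p = 0.354). Of 16 HIF target genes, Ndrg1 (2.34), the lactate dehydrogenase gene Ldha (2.33, at 814 ± 289 against 157 ± 28.9 RPKM) and the peptide gene Adm (1.78) were higher in the carotid body, 0 were lower and 13 were not called. The same 3 passed adjusted over the list alone, and camera gave an adjusted p of 0.354. The carotid body libraries behind the Epas1 and HIF target values were also higher in vessel markers. These were 12 of 16 for endothelium and 15 of 16 for smooth muscle and pericytes.

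Ndufa4l2, a mitochondrial NDUFA4-like protein, was at 815 ± 393 RPKM in the carotid body against 130 ± 71.6 in the adrenal medulla (log2 2.73 ± 0.52, adjusted p = 0.00541), and the cytochrome c oxidase isoform Cox4i2 at 15.2 ± 11.4 against 0.655 ± 0.445 RPKM (3.11, adjusted p = 0.00110). Cox6b2 was higher by 2.20. This list of atypical subunits also holds Higd1c and Pcx, an enzyme gene that encodes no respiratory subunit. Of its 8 tested members, 5 were higher in the carotid body, 1 (Higd1a) was higher in the adrenal medulla and 2 were not called. Vessel markers were higher in the same libraries, with 15 of 16 for smooth muscle and pericytes and 12 of 16 for endothelium. The 2 not called, Cox7a1 and Cox8b, are also abundant in brown fat. Cox7a1 was at 107 RPKM in carotid body pool 2 against 8.07 and 13.4 in pools 1 and 3, and at 88.7 in adrenal medulla pool 3. Cox8b was highest in carotid body pool 3, at 1021 RPKM against 334 and 531 in pools 1 and 2. Adjusted over the list alone the counts were 5 and 1, and camera gave 0.0203, or adjusted p = 0.302 with an estimated correlation and 0.0543 with no filter on low values. The complex I list held 37 genes, among them Ndufa4, a subunit of complex IV. Of these, 0 were higher in the carotid body, 1 (Ndufc1) was higher in the adrenal medulla and 36 were not called. Adjusted over the list alone, 0 were called. Ndufc1 differed by -0.95 (adjusted p = 0.0254) and lost its call without carotid body pool 1 (0.0800), 2 (0.0634) or 3 (0.0606) or adrenal medulla pool 2 (0.126), and without both carotid body pool 2 and adrenal medulla pool 3 (0.0505). The list's median was -0.27 and its camera adjusted p 0.0283, against 0.0516 without carotid body pool 3, 0.683 without adrenal medulla pool 3, 0.189 under quantile scaling and adjusted p = 0.609 with an estimated correlation. Fry did not call the list (adjusted p = 0.297). Without carotid body pool 2 and adrenal medulla pool 3 its median was 0.00128, with a camera adjusted p of 0.727. None of 39 subunits of complexes II to V was called, 0 also adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.109). Without carotid body pool 2, adrenal medulla pool 1 or adrenal medulla pool 2, that list was called at 0.0297, 0.0456 and 0.0373. These are at the preset correlation, and with all libraries an estimated correlation gave a camera adjusted p of 0.596.

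Of 8 tested gas-messenger enzymes and guanylate cyclase subunits, the endothelial nitric oxide synthase gene Nos3 was higher in the carotid body (1.42, adjusted p = 0.00423) and Cth, a hydrogen sulphide producing enzyme, was higher in the adrenal medulla (-2.60, adjusted p = 5.77e-04). The other 6, including Hmox2 and Cbs, were not called; adjusted over the list alone the counts were 1 and 1, and camera gave 0.878. Among 8 NADPH oxidase genes, 4 were higher in the carotid body, 0 were higher in the adrenal medulla and 4 were not called, with 4 adjusted over the list alone and a camera adjusted p of 0.202. Nox4, a constitutively active oxidase, was at 7.79 ± 1.29 against 1.13 ± 0.938 RPKM (log2 2.12). Cyba (1.56) and Ncf4 (0.85), 2 of the 4, both lost their calls without carotid body pool 3 (0.102 and 0.116), adrenal medulla pool 1 (0.0767 and 0.102) or adrenal medulla pool 2 (0.0803 and 0.0931), and with no filter (0.0520 and 0.0573). Cyba also lost its call without carotid body pool 1 (0.107) and under median-ratio scaling (0.0536), and Ncf4 without carotid body pool 2 (0.0767) and under quantile scaling (0.0771). Cyba was at 2.26 (adjusted p = 0.00292) without carotid body pool 2 and adrenal medulla pool 3.

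Potassium channel genes differed in both directions. Kcnk3, the acid-sensitive background channel TASK-1, was higher in the adrenal medulla, at 149 ± 72.0 against 43.4 ± 6.58 RPKM in the carotid body (log2 -1.66 ± 0.33, adjusted p = 0.00715). Kcnk2, the stretch-sensitive TREK-1, also differed in that direction (-3.84, at 1.33 ± 0.511 against 32.0 ± 3.89 RPKM). Kcnk9, which encodes TASK-3, stayed below the filter in both tissues, with 4 reads over the carotid body libraries and 22 over the adrenal medulla libraries. Kcnk6 was the 1 of 6 tested background channels higher in the carotid body, 2 were higher in the adrenal medulla and 3 were not called; the counts adjusted over the list alone were the same, and camera gave 0.109. The call of Kcnk6 (0.71, adjusted p = 0.0283) ended without any 1 of the 3 carotid body pools (0.0720, 0.0678 and 0.0884) and without adrenal medulla pool 1 (0.107), and also under quantile scaling (0.0801) and without carotid body pool 2 and adrenal medulla pool 3 (0.0568). The delayed rectifier genes Kcna1 (60.1 ± 13.7 against 1.53 ± 0.314 RPKM, log2 4.57), Kcna6 (3.26) and Kcna2 (3.02) were higher in the carotid body, and the calcium-activated Kcnn2 was higher in the adrenal medulla (-2.63). Among 19 voltage- and calcium-gated potassium channel genes 9 were higher in the carotid body, 3 were higher in the adrenal medulla and 7 were not called (camera adjusted p = 0.0939, or 0.0443 at a filter of 5 RPKM), with 9 and 4 adjusted over the list alone. In the same libraries 15 of 15 glia and Schwann cell, 7 of 16 neuron and 15 of 16 smooth muscle and pericyte markers were higher in the carotid body. Cortex markers were higher in the adrenal medulla, 16 of 16.

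Of 9 voltage-gated calcium channel genes, Cacna2d3 (1.61) and Cacna1i (1.17) were higher in the carotid body, the auxiliary subunit gene Cacnb2 (-1.51) was higher in the adrenal medulla and 6 were not called. The counts were 2 and 2 adjusted over the list alone, camera gave 0.994, and the median of 0.00444 turned negative without carotid body pool 1 or 2 or adrenal medulla pool 1 or 3, the lowest value being -0.152 without adrenal medulla pool 3, and also under median-ratio (-0.0161) and quantile (-0.208) scaling. Trpv4 (1.97), an osmotic and mechanical sensor, and Trpv6 (1.61), a calcium channel, were among 4 of 12 acid, TRP and HCN channel genes higher in the carotid body. Asic4 (-3.86) was 1 of 2 higher in the adrenal medulla, and 6 were not called; adjusted over the list alone the counts were 5 and 2, and camera gave 0.259. Trpc5 (1.17), another of the 4, lost its call without carotid body pool 1 (0.0992) or 2 (0.0502) or adrenal medulla pool 2 (0.102) or 3 (0.0511), without carotid body pool 2 and adrenal medulla pool 3 (0.0684) and with no filter (0.0521).

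Receptors for transmitters and hormones also parted in both directions. Adora2a, an adenosine receptor gene, was at 11.0 ± 2.68 RPKM in the carotid body and 0.580 ± 0.185 in the adrenal medulla (log2 2.91 ± 0.23, adjusted p = 5.70e-05). P2ry12, an ADP receptor gene of platelets and microglia, was higher there by 3.48, or 4.11 without carotid body pool 1 and 2.62 (adjusted p = 0.0149) without carotid body pool 2 and adrenal medulla pool 3. Drd2, the dopamine D2 receptor gene, was not called, at 2.66 ± 1.16 against 1.04 ± 0.179 RPKM (log2 0.79, adjusted p = 0.0631), though it was called without carotid body pool 1 (1.09, adjusted p = 0.00785) and with the replicate block (adjusted p = 0.0286). Mc2r, the corticotropin receptor (-6.36), the angiotensin receptor gene Agtr2 (-5.68) and the neuropeptide Y receptor gene Npy2r (-3.77) were higher in the adrenal medulla. Agtr2 became -5.08 without adrenal medulla pool 2 and -6.38 without adrenal medulla pool 3, or -6.39 with carotid body pool 2 left out as well. Of 38 tested G protein-coupled receptor genes, 16 were higher in the carotid body, 9 were higher in the adrenal medulla and 13 were not called (camera adjusted p = 0.168), with 20 and 10 adjusted over the list alone. Mc2r is also in the adrenal cortex list, of which 16 of 16 tested members were higher in the adrenal medulla. Glia markers (15 of 15) and smooth muscle and pericyte markers (15 of 16) were higher in the carotid body.

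Only 5 of 1133 olfactory receptor genes passed the filter. Olfr78 and Olfr558 (12.8 ± 1.85 against 0.102 ± 0.0572 RPKM, log2 3.64, adjusted p = 1.11e-05) were higher in the carotid body, 0 were higher in the adrenal medulla and 3 were not called. The same 2 passed adjusted over the list alone, and camera gave 0.0110, or adjusted p = 0.206 with an estimated correlation. With no filter on low values the list lost its call (adjusted p = 0.226) and its median became -0.0335. Regulators of G protein signalling included Rgs5 and Rgs4 (292 ± 129 against 33.7 ± 8.11 RPKM, log2 3.01) in the carotid body and Rgs2 (-2.52, or -3.26 without carotid body pool 2 and adrenal medulla pool 3) and Rgs11 (-1.58) in the adrenal medulla. Of 12 tested, 5 were higher in the carotid body, 3 were higher in the adrenal medulla and 4 were not called, the counts adjusted over the list alone were 5 and 3, and camera gave 0.283. Adcy4 (2.32), an adenylyl cyclase, and the calmodulin-dependent phosphodiesterase genes Pde1b (2.34) and Pde1a (1.29) were among 9 of 22 cyclic nucleotide genes higher in the carotid body. Another 2 were higher in the adrenal medulla and 11 were not called, with 10 and 5 adjusted over the list alone and a camera adjusted p of 0.109, or 0.0176 with no filter and 0.0426 at a filter of 5 RPKM. Of 25 ligand-gated channel genes, 5 were higher in the carotid body, 5 were higher in the adrenal medulla and 15 were not called, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.970). The ATP-gated P2rx7 (1.71) was among the first, and the nicotinic subunit gene Chrnb4 (-1.62) and the glutamate receptor gene Gria3 (-1.84) among the second. The median of this list, 0.147, was -0.0353 without adrenal medulla pool 3 and -0.0280 under quantile scaling. Gria2, another of those higher in the adrenal medulla, lost its call without carotid body pool 1 (0.102) or 3 (0.0807) or adrenal medulla pool 1 (0.0754) or 2 (0.0908).

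Hox genes record position along the body axis. All 13 tested genes of paralogue groups 5 to 13 were higher in the adrenal medulla, also adjusted over the list alone, with a median of -2.71. Hoxb7 stood at 47.8 ± 9.46 RPKM in the adrenal medulla and 0.168 ± 0.163 in the carotid body (SD, n = 3; log2 -5.38 ± 0.23), and Hoxb9 at 31.3 ± 4.05 and 0.179 ± 0.154 RPKM (-4.78). The list passed camera at an adjusted p of 5.26e-15, and at adjusted p = 0.0352 with an estimated correlation. Members such as Hoxb7, Hoxb9, Hoxb6 and Hoxc6 reached 1 RPKM in adrenal medulla libraries only, so passing the filter fixed their direction. The count of 13 and the camera values are limited by this. The other 14 of 27 members of the list were not tested. Of 8 tested genes of groups 1 to 4, Hoxa2 (2.20, at 5.10 ± 0.553 against 0.334 ± 0.230 RPKM), Hoxa3 (1.09) and Hoxa4 were higher in the carotid body. Hoxc4 (-2.79), Hoxb4 (-1.28) and Hoxd4 were higher in the adrenal medulla and 2 were not called. The counts were 3 and 3 adjusted over the list alone, and camera gave 0.446. The call of Hoxa3 ended without adrenal medulla pool 2 (adjusted p = 0.0627). The adrenal medulla libraries behind the Hox values also held transcripts of cortex markers, with 16 of 16 cortex markers higher there.

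**Figure D3:**
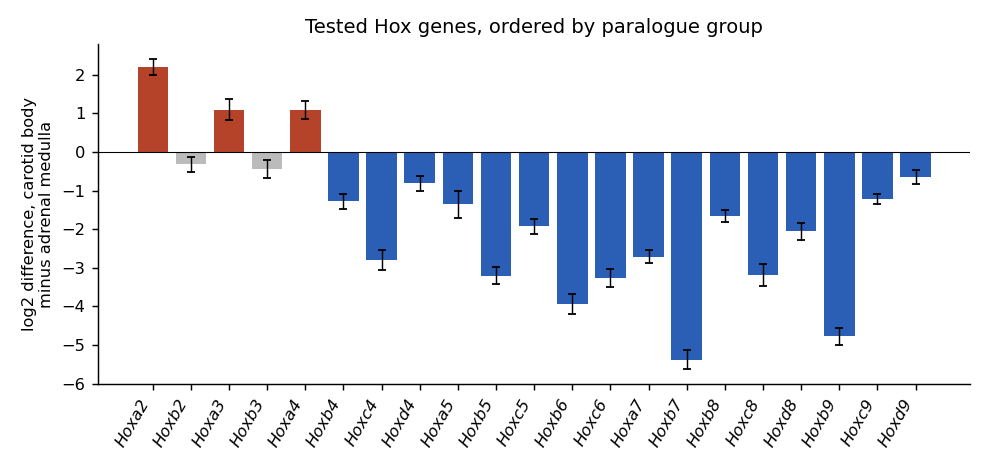
Log2 difference, carotid body minus adrenal medulla, of the tested Hox genes in order of paralogue group, with bars of ± 1 SE from 3 libraries per tissue (red, higher in the carotid body; blue, higher in the adrenal medulla; grey, not called). The 13 genes of groups 5 to 13 all lie below 0, down to -5.38 for Hoxb7, while Hoxa2 lies at 2.20.

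Imprinted genes included Dlk1, a membrane protein related to Notch ligands, at 417 ± 71.2 RPKM in the adrenal medulla and 16.9 ± 6.26 in the carotid body (log2 -4.58, adjusted p = 2.22e-05). The noncoding RNA gene Meg3, from the same imprinted region, differed by -2.65. The noncoding RNA gene H19 lay in the other direction, with 1818 reads over the carotid body libraries against 18 over the adrenal medulla libraries (3.89, adjusted p = 1.11e-05). Of 17 tested, 2 (H19 and Igf2) were higher in the carotid body, 5 were higher in the adrenal medulla and 10 were not called, with 2 and 5 adjusted over the list alone and a camera adjusted p of 0.188, or 0.0472 with no filter on low values. Rian, 1 of the 5 (-2.54, adjusted p = 0.00960), was at -2.28 and lost its call without carotid body pool 1 (adjusted p = 0.0505), and was at -1.89 without adrenal medulla pool 2.

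Markers of vessels, nerve sheath and connective tissue were higher in the carotid body libraries. Acta2, smooth muscle actin, was at 625 ± 189 RPKM against 22.1 ± 1.13 (SD, n = 3; log2 4.72 ± 0.26, adjusted p = 1.41e-05), and the myosin genes Myh11 (3.98) and Myl9 (3.90) followed. Of 16 smooth muscle and pericyte markers 15 were higher in the carotid body, 0 were lower and 1 (Des) was not called, with 15 adjusted over the list alone (camera adjusted p = 1.24e-11, adjusted p = 0.0630 with an estimated correlation). All 15 tested glia and Schwann cell markers were higher, also adjusted over the list alone, among them the calcium-binding protein gene S100b (3.27, at 137 ± 18.9 against 13.4 ± 2.88 RPKM), the myelin gene Mbp (2.85) and the transcription factor gene Sox10 (2.98). Camera gave 1.02e-10 for this list, and adjusted p = 0.130 with an estimated correlation. The collagen-binding proteoglycan gene Dcn (1850 ± 227 against 79.4 ± 51.0 RPKM, log2 4.74), Col3a1 (3.88), Lum (4.19) and Mfap5 were among 16 of 18 fibroblast and matrix markers higher in the carotid body, while 0 were lower and 2 were not called. Col3a1 became 4.64 without carotid body pool 1 and Lum became 3.59 without adrenal medulla pool 3. Without carotid body pool 2 and adrenal medulla pool 3, Col3a1 was at 3.22 (adjusted p = 0.0335), Lum at 3.23, Dcn at 4.12 and Cldn5, named below, at 4.95. This list again had 16 adjusted over the list alone and a camera adjusted p of 1.02e-10, with adjusted p = 0.174 with an estimated correlation. Of 16 endothelial markers, 12 were higher in the carotid body, 0 were lower and 4 were not called, with 13 adjusted over the list alone, led by the tight junction gene Cldn5 (4.26) and followed by Sox17 (2.73), Vwf (2.43) and Sox18 (2.27). Camera gave 1.01e-06, and adjusted p = 0.130 with an estimated correlation.

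Neuron markers were mixed, with 7 of 16 higher in the carotid body, 1 higher in the adrenal medulla and 8 not called. Gap43 headed the 7, followed by Thy1 (2.65), Sncg (2.31) and Prph (1.80), an intermediate filament gene of peripheral neurons. Adjusted over the list alone the counts were 7 and 2. The camera adjusted p was 0.0254, against 0.0529 without carotid body pool 3, 0.0513 without adrenal medulla pool 1, 0.0522 without adrenal medulla pool 3 and adjusted p = 0.421 with an estimated correlation. Macrophage markers were higher in the carotid body for 5 of 13, led by the scavenger receptor gene Cd163 (1.69) and the growth factor receptor gene Csf1r (1.36), with 0 lower and 8 not called, and 5 adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.174 with an estimated correlation). Of the 5, Aif1 (1.24) and Mrc1 (1.21) lost their calls without carotid body pool 1 (0.0602 and 0.0618), Aif1 also without adrenal medulla pool 1 (0.0836) or 2 (0.0701), and Mrc1 without carotid body pool 2 (0.0654). Of 5 erythroid markers, 4 were higher in the carotid body, among them Alas2 (1.69), the first enzyme of haem synthesis in red cells, with 0 lower and 1 not called. All 5 passed adjusted over the list alone, and camera gave 0.0138, or adjusted p = 0.520 with an estimated correlation and 0.0620 with no filter on low values. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-b1 lost their calls without carotid body pool 1 (adjusted p = 0.160, 0.151 and 0.111), without carotid body pool 3 (0.157, 0.149 and 0.103), without adrenal medulla pool 1 (0.133, 0.126 and 0.0948) and without adrenal medulla pool 2 (0.152, 0.145 and 0.115). They also lost them with no filter (0.0962, 0.0912 and 0.0590) and under median-ratio scaling (0.0865, 0.0831 and 0.0693), and the first 2 at a filter of 5 RPKM (0.0540 and 0.0504) and with every row of the table tested (0.0632 and 0.0599), and Hba-a1 with a pseudocount of 0.01 (0.0520). Their differences rose from 1.83, 1.80 and 1.40 to 2.82, 2.75 and 2.02 (adjusted p = 7.75e-04, 8.20e-04 and 0.00267) without carotid body pool 2 and adrenal medulla pool 3. Hba-a1 and Hba-a2 are near-identical copies whose reads cannot be told apart.

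**Figure D4:**
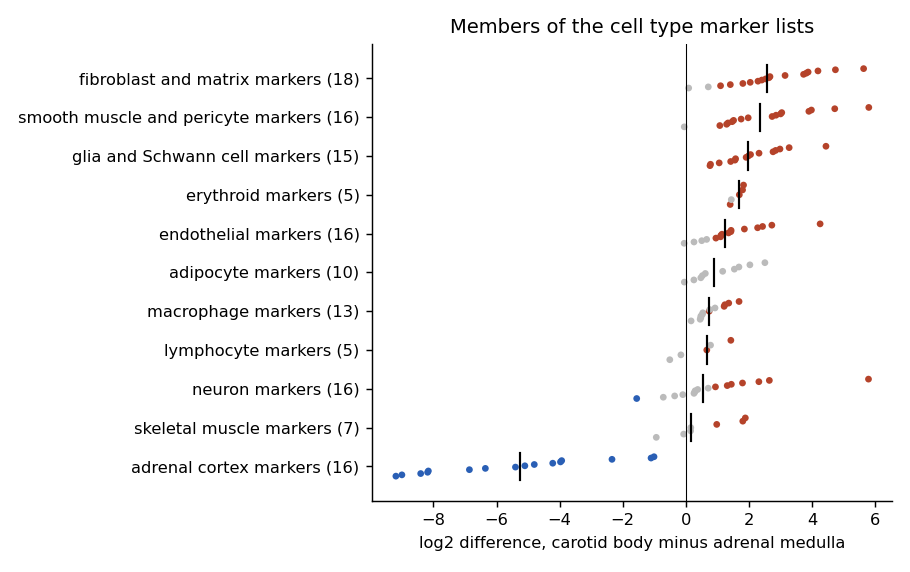
Log2 difference, carotid body minus adrenal medulla, of each tested member of the cell type marker lists (points; number tested in brackets), with a vertical tick at each list's median (red, called higher in the carotid body; blue, called higher in the adrenal medulla; grey, not called). Medians run from 2.58 for fibroblast and matrix markers to -5.25 for adrenal cortex markers.

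Of 7 tested skeletal muscle markers, Tnni2 (1.88), Tnnt3 (1.80) and Tnnt1 (0.98), troponins of muscle fibres, were higher in the carotid body, 0 were lower and 4 were not called, with 3 adjusted over the list alone (camera adjusted p = 0.188). Under quantile scaling Tnnt1 was at 0.76 and lost its call (adjusted p = 0.0596). Of 5 lymphocyte markers, the cytokine receptor gene Il7r (1.43) and Cd3d (0.66) were higher in the carotid body, 0 were lower and 3 were not called, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.421). Cd3d lost its call without carotid body pool 1 (adjusted p = 0.0693) or 2 (0.0541) and without adrenal medulla pool 1 (0.0578) or 2 (0.0819), and under quantile scaling (0.114), without the trend (0.0506), with voom (0.0552) and without carotid body pool 2 and adrenal medulla pool 3 (0.0632). None of 10 adipocyte markers was called, 0 also adjusted over the list alone (camera adjusted p = 0.446). Their levels parted the pools of both tissues. In the adrenal medulla, Adipoq was at 68.0, 2.73 and 79.8 RPKM and Cfd at 275, 11.6 and 1641 in pools 1, 2 and 3, and in the carotid body they were at 26.7, 338 and 53.0 and at 189, 669 and 507. Ucp1, the uncoupling protein of brown fat, was at 221 RPKM in carotid body pool 2 and at 0 and 2.23 in pools 1 and 3, against 0, 0.128 and 2.48 in the adrenal medulla pools. The 9 thyroid and parathyroid markers all stayed below the filter, with 0 tested.

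Sex-linked genes set adrenal medulla pool 3 apart. The Y-linked genes Ddx3y and Eif2s3y were not called between the tissues (0.58 and 0.72, adjusted p = 0.803 and 0.749), nor was the third tested member, Uty, and 0 were called adjusted over the list alone. The Y-linked genes of the list held 7 reads in adrenal medulla pool 3, against 3060 and 3277 in pools 1 and 2 and 1292 to 2178 in the carotid body pools. Without adrenal medulla pool 3, Ddx3y and Eif2s3y were lower in the carotid body (-1.08 and -0.93, adjusted p = 0.0303 and 0.0475), also with carotid body pool 2 left out as well (-1.36 and -1.21). Of 9 immediate early genes, Fos (1.41), Atf3 (1.21) and Zfp36 (1.13) were higher in the carotid body, Nr4a1 (-1.57) was higher in the adrenal medulla and 5 were not called, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.484). Zfp36 lost its call without carotid body pool 1 (0.0883) or 2 (0.0775) and without adrenal medulla pool 1 (0.0501). Of 9 heat shock genes, Hspb1 (1.42), Hspa1a (1.16) and Hspa1b (0.94) were higher in the carotid body, 0 were lower and 6 were not called, with 3 adjusted over the list alone. The median of that list was -0.12 and its mean 0.19, with camera's direction upward at an adjusted p of 0.970. Hspa1a lost its call without carotid body pool 3 (0.0516) or adrenal medulla pool 2 (0.0544), and its near-identical neighbour Hspa1b without any 1 carotid body pool (0.0951, 0.0549 and 0.107) or adrenal medulla pool 2 (0.128). Without carotid body pool 2 and adrenal medulla pool 3, Zfp36 (0.0814) and Hspa1b (0.0554) also lost theirs.

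**Figure D5:**
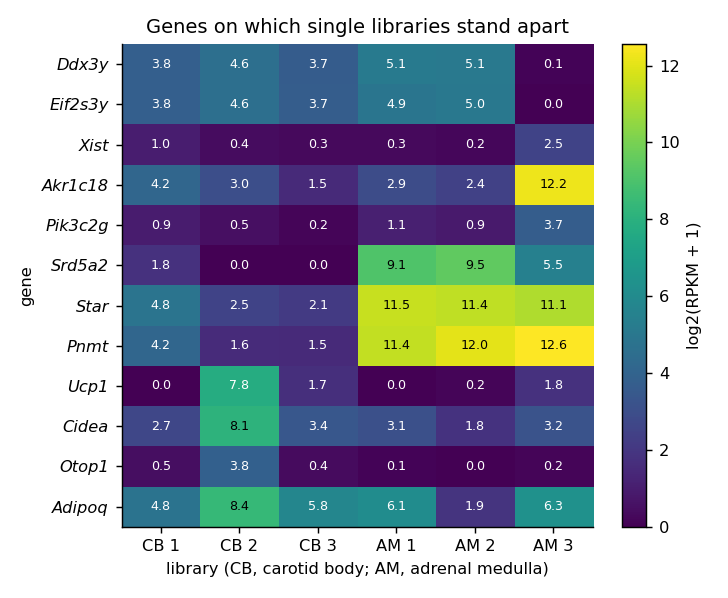
Log2(RPKM + 1), by colour and as a number, of genes on which a single library stood apart, in the 3 carotid body (CB) and 3 adrenal medulla (AM) libraries. Ddx3y and Eif2s3y are near 0 in adrenal medulla pool 3, where Akr1c18 is high, and Ucp1, Cidea and Otop1 are high in carotid body pool 2.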

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

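Of the tests in this part, the count of genes called by other divisions of the libraries and the fit of the entries without a length were chosen after the result was seen. A signal appeared in data outside the main comparison, in the entries of the table that have no mRNA length and hold raw reads. Of these, 1181 had more than 3 reads in every library. Col12a1, a collagen of tendons and ligaments, was at 70.3 ± 15.5 CPM in the carotid body and 3.07 ± 1.202 in the adrenal medulla (SD, n = 3 pools each), a log2 difference of 4.59 by limma's voom over 15695 entries (adjusted p = 8.25e-05). Aff3, a nuclear factor of the AFF family, was higher there by 3.67 and Adamtsl5, a secreted matrix protein, by 3.39 (adjusted p = 3.50e-04 and 3.49e-04). These genes are named because of their values. Of 28 curated entries tested, 6 were higher in the carotid body and 1 was higher in the adrenal medulla, and of 1068 predicted ones 141 and 32. The macrophage marker Cd68, missing from its list for want of a length, was not called (-0.16, adjusted p = 0.818). CPM values take no account of transcript length, so they compare tissues and not genes.

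The 6 libraries can be divided into 3 and 3 in 10 ways, and the division by tissue was set against the other 9. By tissue, limma called 2929 genes, and the highest of the other divisions called 0, where between 25 and 1959 genes had an unadjusted p under 0.05. For genes over 2-fold apart the numbers were 722 and 0. In both cases 1 of the 10 divisions, the real one, gave as many, and 10 divisions are too few for a share under 0.05. Each of the other 9 also placed libraries of both tissues on both sides. The tissue difference therefore added to the spread within their groups, which works against calling genes. Their 0 called genes are thus no measure of what chance gives, and no conclusion is drawn from them. For gene lists at the preset correlation, the tissues gave 15 calls, but 2 of the 10 divisions gave as many, since carotid body pools 1 and 2 with adrenal medulla pool 3 against the rest called 16. That division and 3 others, the real one among them, separate the libraries of every pool number, 4 in all, and the others of these called 14 and 9 lists. Again the divisions are too few for a share under 0.05. The other divisions also mix the tissues unequally, so they keep part of the tissue difference. Their list calls are therefore no measure of chance and cannot set the weight of a list call at the preset correlation. Such a call was not read by itself. For each list called in the main comparison, the counts of called members and the value with an estimated correlation stand beside it.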

How the results depend on the processing

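In this part, voom on the recovered reads, the replicate block with the length trend removed, and the fit without carotid body pool 2 and adrenal medulla pool 3 were chosen after the data were examined. Of 135 genes of the naming rule, 130 were called. Of these, 111 kept their calls in every alternative that tested them, 98 of which were tested in all 19, and 0 of the called ones reversed. No gene called in either direction was called in the other direction under any alternative. Leaving out 1 library gave 1460 to 1999 genes higher in the carotid body, 692 to 1464 higher in the adrenal medulla, 346 to 466 and 178 to 296 over 2-fold apart, and 13 to 16 lists. With the pool number as a replicate block, 2257 and 1356 genes were called, and the only call to change among the named genes and lists was that of Drd2 (adjusted p = 0.0286), which the block with the length trend removed also called. Under quantile scaling, 55.0% of calls went to the carotid body.

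At a filter of 5 RPKM, 1103 and 632 of 8872 tested genes were called. With a pseudocount of 0.1, 729 genes were over 2-fold higher in the carotid body, and with voom 746; the cause was not tested. Without carotid body pool 2 and adrenal medulla pool 3, 2067 genes were higher in the adrenal medulla; the cause was not tested beyond the patterns of those pools. Of 15 called lists, 10 kept their calls outside the other list tests. Camera with an estimated correlation called 2 lists, the adrenal cortex markers and the Hox genes of groups 5 to 13. Its adjusted p rose also where the estimate lay below the preset 0.01. For that Hox list the estimate was -0.00366, and the camera adjusted p went from 5.26e-15 to 0.0352. For background potassium channels it was 0.00294, and the camera adjusted p went from 0.109 to 0.321. A higher correlation does not account for these rises. A call lost with an estimated correlation therefore does not by itself show that a list's genes vary together. The cause was not tested further. Fry called 22.

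Medians of lists that reversed lay near 0 in most cases, and the cause was not tested. The neuropeptides were at -1.19 at 5 RPKM, where fewer were tested, and fry, where they were not called (adjusted p = 0.582), gave a downward sign with the median still at 0.483. Calcium channels were at -0.0161 under median-ratio scaling, -0.208 under quantile scaling, -0.239 without both pools, and -0.152 to 0.0257 without 1 library. The HIF pathway was at -0.00829 at 5 RPKM, -0.0254 and -0.0567 under those scalings, and -0.0737 to 0.275 without 1 library. Gas-messenger enzymes were at 0.0592 and 0.0588 with pseudocounts of 0.1 and 0.01, 0.0593 with voom, 0.00322 with the block and length trend, 0.0959 without both pools, and -0.0671 to 0.0989 without 1 library. Ligand-gated channels were at -0.118 at 5 RPKM, -0.0280 under quantile scaling, -0.185 without both pools, and -0.0353 to 0.282 without 1 library. Olfactory receptors were at -0.0335 with no filter, where receptors with few reads enter and the list lost its call (adjusted p = 0.226), and complex I was at 0.00128 without both pools.

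Among single genes, Ddx3y and Eif2s3y were at -1.36 and -1.21 without both pools, and ranged from -1.08 to 1.42 and from -0.93 to 1.58 without 1 library, since adrenal medulla pool 3 held hardly any Y-linked reads. Hif1a was at -0.0605 under quantile scaling, -0.79 (adjusted p = 0.0383) without both pools, and -0.48 to 0.36 without 1 library; the cause was not tested. Depth limits low genes most, as 1 read on a 2 kb mRNA amounts to 0.0304 to 0.0377 RPKM against the filter of 1 RPKM.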

Other observations

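Of the tests below, the mast cell and lymphatic lists, the carotid body label and same-mice tests of adrenal medulla pool 3, the white fat test and both tests of cortex transcripts were chosen after the result was seen. The mast cell proteases Mcpt4 (44.6 ± 11.7 against 0.212 ± 0.0889 RPKM, SD, n = 3, log2 5.20), Cma1 (87.0 ± 23.3 against 1.73 ± 0.824, log2 5.02), Cpa3 (4.65) and Tpsb2 (4.26) were higher in the carotid body. Of 9 mast cell genes listed after Cma1 and Mcpt4 were seen, 7 were tested and 7 were higher there by limma. They included Fcer1a (2.01), the alpha subunit of the IgE receptor, and the stem cell factor receptor gene Kit (1.00). Members such as Mcpt4, Tpsb2 and Fcer1a reached 1 RPKM in carotid body libraries only, so passing the filter nearly fixed their direction. Hdc, not tested, had 122 reads over the carotid body libraries and 328 over the adrenal medulla libraries, mostly in pool 3. Ccl21a, a chemokine that draws in lymphocytes and dendritic cells, was at 36.2 ± 14.6 RPKM in the carotid body against 0.109 ± 0.133 (adjusted p = 1.71e-05), a value made uncertain by near-identical Ccl21 copies in the genome. Of 7 lymphatic vessel genes listed after Ccl21a was seen, 4 were higher in the carotid body, with Mmrn1 (2.40), Lyve1 (2.03) and Reln (1.40), while Prox1, a transcription factor of lymphatic identity, was higher in the adrenal medulla (-1.46) and 2 were not called. No test of either list as a whole was run.

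A few transcription factor genes were picked from the table for their values. Dlx5, a factor of craniofacial development, was at 13.2 ± 0.503 RPKM in the carotid body against 0.130 ± 0.0601 (SD, n = 3, log2 3.66, adjusted p = 1.10e-05). Barx1, a factor of jaw and stomach development, had 266, 257 and 428 reads in the carotid body libraries and 0 in each adrenal medulla library. Hmx3, a factor of inner ear development, had 145, 210 and 359 reads in the carotid body libraries and likewise 0 in each adrenal medulla library.

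Adrenal medulla pool 3 held 7 Y-linked reads, against 3060 and 3277 in pools 1 and 2. Loss of transcripts of that abundance was argued against, since 0% of 4406 other genes at 10 to 60 RPKM in pools 1 and 2 had as low a ratio as Ddx3y, and so was a carotid body library under the wrong label, since cortex markers had a median ratio of 0.899 to pools 1 and 2 (range 0.441 to 3.24). Carotid body pool 3 held 1292 Y-linked reads, which argues against both tissues numbered 3 coming from the same mice. Adrenal glands of female mice are a candidate explanation that remained, as Akr1c18 and Pik3c2g, genes of the adrenal X-zone that persists in female mice, were 880 and 11.8 times their level in pools 1 and 2 and Xist was 22.6 times, with Akr1c18 at 4797 against 6.56 and 4.35 RPKM; of these X-zone genes only Akr1c18 passed the filter, and it was not called between the tissues. The labels give no sex, so a difference in sex between pools stays open, as does an adrenal sample from outside the stated pools.

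Carotid body pool 2 was rich in adipocyte transcripts, with the adiponectin gene Adipoq at 338 RPKM against 26.7 and 53.0 in pools 1 and 3, and the lipid droplet gene Cidea at 276 against 5.33 and 9.71. Adipoq also parted the adrenal medulla pools, at 68.0, 2.73 and 79.8 RPKM in pools 1, 2 and 3, while Cidea was at 7.35, 2.59 and 8.20; fat in those pools was not tested. White fat alone was argued against by Ucp1, at 221 RPKM. Brown fat tissue in the pool may be the source, as 8 further brown fat genes had a median log2 ratio of 2.07 to pools 1 and 3, from -0.35 for Cox8b, which the other carotid body pools also express, to 5.40 for Cpt1b, with 5 of 8 over 2-fold higher. Between the tissues 4 of the 8 were tested and 1, Ppargc1a, was higher in the carotid body; Cox7a1 and Cox8b are also in the list of atypical subunits. The design gives no group that would test a biological explanation.

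Steroid synthesis genes were high in every adrenal medulla pool, with Hsd3b1 at 3642 ± 1363 and Star at 2582 ± 402 RPKM (SD, n = 3). The count of cortex markers higher there, 16 of 16 tested, restates the pattern. The libraries are of whole dissected tissue, so cortex tissue in the medulla pools and expression by medullary cells themselves cannot be told apart. Whether dilution of chromaffin transcripts by cortex RNA set the higher Ddc of the carotid body also stays open. The median log2 difference of Th, Dbh, Chga and Chgb was -3.41, but levels per chromaffin cell are unknown, so dilution and a difference per cell cannot be told apart.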
